A study of Mus musculus with 8 samples.

How the data were processed

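RNA was measured in single cells of 8 libraries from subcutaneous 4T1 tumours of Balb/c mice, collected after 10 days. Per the labels, tumour pieces were digested for 1 h with a bacterial protease in a gentleMACS instrument, at 37C or 4C. The 37C tubes ran on an instrument with heaters and the 4C tubes on one without, so instrument and temperature changed together. The labels give an inhibitor as present or absent, and the protocol names actinomycin D at 2 nM. Red cells were lysed, and debris and dead cells were removed. Libraries were made with the SureCell 3' kit on the ddSEQ system. Each of the 4 conditions had 1 suspension, a pool of 6 pieces from different mice, divided into the aliquots A and B.

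The 8 deposited library tables hold raw counts, molecules (UMIs) per gene and barcode, not normalised; 2990 to 3000 barcodes were listed per library, and the rule for listing them is not given in the sources used here. The deposited expression table of 654 cells and 6933 genes holds the natural log of 1 plus counts per 10000, which was checked on the values: 99.9956% of those above 0 were proportional to the raw counts of the same barcode within a tolerance of 0.001. The deposited cell annotation names a library and 1 of 4 cell types for each of these 654 cells. For the series the authors name UMI-tools, STAR 2.7.1a, featureCounts 1.6.0, SAMtools, Seurat and the build GRCm38; their settings, the filters on cells and genes, the handling of doublets and the way cell types were named are not given in the sources used here. Of 17580 gene identifiers, 17520 received a symbol, 12505 of them with the same identifier version in the annotation used, and the others were matched without the version.

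Raw counts were summed over the annotated cells of each library. Totals of these sums were 158314 to 199929 UMIs at 37C and 23212 to 65149 at 4C. Genes were kept by filterByExpr (3391 genes) and scaled by TMM. A model with 4 groups was fitted with edgeR 4.0.16 under R 4.3.3 (glmQLFit and glmQLFTest, two-sided), and p-values were adjusted by the Benjamini-Hochberg method. Genes with an adjusted p under 0.05 were called. The 6 contrasts were temperature averaged over inhibitor, temperature without and with inhibitor, inhibitor at 37C and at 4C, and the interaction. Pairs of libraries from 1 suspension differed by more than the counting noise of UMIs (chi-square per degree of freedom 1.53 to 2.05). That statistic treats each UMI as an independent draw, so the sampling of cells is not separated from the excess. The p-values of this 4-group model measure only the spread between aliquots of 1 suspension per condition. The alternative with aliquots summed has 1 suspension per condition and additive terms for temperature and inhibitor. Its p-values for temperature take the interaction and the difference between suspensions together as spread, so no spread between like suspensions was measured.

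Tests within a cell type were planned for types with at least 20 cells in every library, which left 0 types. Those reported come from a minimum of 10 cells, listed beforehand as a second choice, which admitted tumour cells (1756 genes) and T cells (230 genes).

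Named genes followed a rule fixed before the data were examined. For temperature, it took the 10 largest increases and 10 largest decreases among called genes with a mean log2 CPM of at least 5 and the same sign without and with inhibitor. For each inhibitor effect and the interaction it took 5 and 5, and within a cell type 3 and 3. Fos, Jun, Egr1, Atf3, Ier3, Hspa1a, Hspa1b, Cirbp, Rbm3 and members of the fixed lists were named whatever their call. Predicted genes and pseudogenes were counted but not named. The single-gene results of some list members are not reported here.

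The 26 fixed lists covered immediate-early, heat shock, inflammatory NF-kB, cold-inducible, p53, hypoxia and glycolysis, unfolded-protein, type 1 interferon, cell cycle, NRF2, mitochondrially encoded and ribosomal protein genes, and markers of 14 cell types. The 18 with at least 2 tested genes were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation and with fry (limma 3.58.1), adjusted over the lists of a contrast. Single-gene calls in a list were also counted after adjustment over the list alone.

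Cell type shares (percent of a library's annotated cells) and per-cell quality measures were compared by two-sided exact permutation tests, 4 against 4 libraries, with 70 arrangements and a smallest possible p of 0.0286. They treat aliquots as independent, and were adjusted over the 4 types or the 4 measures (SciPy 1.17.1, NumPy 2.4.6, pandas 2.3.3, Python 3.11.15). Where a group had no counts of a gene, the fold is a lower bound from a floor of 3 counts over the group. With 1 to 3 counts, it has an exact (Clopper-Pearson) 95% counting interval. Intervals and floors cover counting error only.

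Alternatives were DESeq2 1.42.0 (size factors, or its Wald test), no filter, an absolute log2 fold change of at least 1, the replicate letter as a block, each library left out, all barcodes, the aliquots of a suspension summed, and equal cell type composition (limma on log2 CPM with 10 added). Thinning every library to the smallest total and adding unannotated barcodes over 5000 UMIs were added after seeing the data. Tested on simulated data with 200 changed genes and a common dispersion, the temperature test called 104 genes, 4 of them falsely, and recovered 27% of 2-fold and 73% of 4-fold changes. For the inhibitor at 4C it recovered 4% and 37%. The simulated libraries were independent and held no spread between suspensions, so these rates may not hold for the real data. Figures were drawn with matplotlib 3.10.9.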

Results

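Tumours grown from 4T1 cells, a mouse mammary carcinoma line, were dissociated at 37C or 4C, without or with actinomycin D, an inhibitor of transcription. Each of the 4 groups had 2 libraries, A and B, which were aliquots of 1 suspension. All barcodes of a library summed to 433245 to 801510 UMIs at 37C and to 55698 to 186002 UMIs at 4C. The annotated cells numbered 99 to 115 per library at 37C and 34 to 74 at 4C. Tumour cells made up 325 of the annotated cells, T cells 154, macrophages 109 and NK cells 66.

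Macrophages took 21.3% ± 6.91 of annotated cells at 37C and 7.45% ± 4.92 at 4C (SD, n = 4 each), and all 4 libraries at 37C lay above every library at 4C. T cells took 16.9% ± 9.07 at 37C and 38.1% ± 6.81 at 4C, with all 4 libraries at 37C below every library at 4C. NK cells took 7.09% ± 4.23 and 15.9% ± 7.23, and tumour cells 54.7% ± 11.2 and 38.6% ± 7.39. In two-sided exact permutation tests p was 0.0286, the smallest the design allows, for macrophages and for T cells, and 0.0571 for NK cells and for tumour cells. After adjustment over the 4 types p was 0.0571 for each, so none passed 0.05. These permutations treat libraries as independent, although A and B are aliquots. A permutation of the 2 suspensions per temperature could not reach a p under 0.05. For libraries with against without inhibitor, the adjusted exact permutation p was 0.971 for each type. That test pools both temperatures and cannot show equal shares within either, since the difference had opposite signs at 37C and 4C in each type. T cells took 24.1% without and 9.60% with inhibitor at 37C, but 34.2% and 42.05% at 4C (means, n = 2 libraries each). Macrophages took 16.5% and 26.1% at 37C, but 8.81% and 6.10% at 4C. Tumour cells took 49.8% and 59.6% at 37C, but 42.6% and 34.5% at 4C, and NK cells 9.54% and 4.63%, but 14.4% and 17.4%. All shares leave out unannotated barcodes, of which 104 at 37C held over 5000 UMIs. Were these cells other than macrophages, 37C no inhibitor B (17 macrophages of 115 cells, 23 such barcodes) would lie below 4C no inhibitor A (8 of 59, 1 such barcode).

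**Figure D1:**
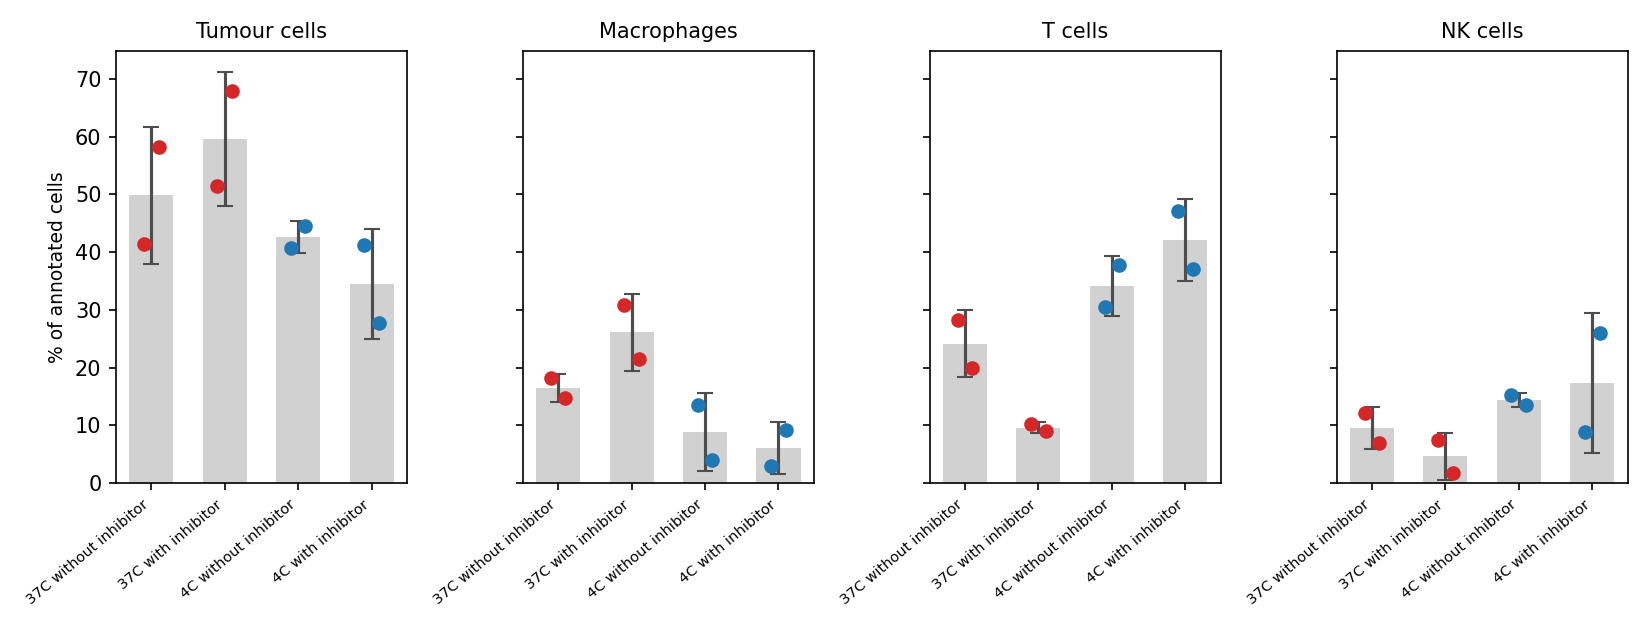
Share of annotated cells (percent, vertical axis) by cell type and group; points are libraries (red 37C, blue 4C), bars the mean of 2 libraries and error bars the SD. All 4 macrophage points at 37C lie above the 4 at 4C, and all 4 T-cell points at 37C lie below the 4 at 4C.

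Cells of the 37C libraries held more molecules and more genes. The median cell had 1299 ± 249.8 UMIs at 37C and 592 ± 30.7 at 4C, and 814 ± 118 and 439 ± 17.0 genes (SD, n = 4 libraries each). Within types the library medians were 1124 to 1807 UMIs at 37C and 977 to 1113 at 4C in tumour cells, and 743 to 1027 and 309 to 400.5 in T cells. The number of annotated cells was 108 ± 6.99 and 55.3 ± 16.5. Each of these 3 differences had an exact permutation p of 0.0286 (two-sided, adjusted 0.0381) over libraries, with aliquots treated as independent. Mitochondrially encoded genes gave 0.105% ± 0.0418 of UMIs at 37C and 0.0724% ± 0.0486 at 4C (exact permutation p = 0.257). The library tables held only 9 such features, so this share is a limited measure of cell quality. With cells thinned to 200 UMIs, the median gene number was 171.2 ± 0.957 at 37C and 172.6 ± 1.601 at 4C (exact permutation p = 0.257).

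The temperature comparison asks which transcripts differ between warm and cold dissociation. Over all annotated cells, immediate-early and inflammatory NF-kB genes were higher at 37C as lists, with the tests given below for each. Fos (ENSMUSG00000021250.13, GRCm38 chromosome 12, 85473890 to 85477273), a subunit of the AP-1 transcription factor, had 665 ± 223 and 354 ± 150 CPM (counts scaled to a common library total) at 37C without and with inhibitor. At 4C it had 0 counts without inhibitor and 91.4 ± 12.7 CPM with it (SD, n = 2 libraries each). Arg1 (ENSMUSG00000019987.8, chromosome 10, 24915221 to 24927484), which encodes arginase, had 1190 ± 98.6 and 1870 ± 458 CPM at 37C, against 265 ± 152 CPM and 0 counts at 4C. The neutrophil-attracting chemokine gene Cxcl3 had 0 counts in all 4 libraries at 4C and was at least 14.7-fold higher at 37C.

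In edgeR's quasi-likelihood test 93 of 3391 genes were higher at 37C and 42 lower. The other increases named by the rule were Pf4, Csf1r, Psap, Nr4a1, C1qa, Clec7a and C1qc. Pf4 was 13.9-fold higher in mean CPM, C1qa 9.55-fold and C1qc 9.13-fold. Csf1r, the receptor for macrophage colony-stimulating factor, had 1 count at 4C and was 34.3-fold higher (95% counting interval 6.35 to 1430). The orphan nuclear receptor gene Nr4a1 was 35.6-fold higher (5.06 to 1150), Psap 29.2-fold (4.54 to 1030) and Clec7a 13.4-fold (4.30 to 980). The decreases named were Traf3ip3, Il16, Rhof, Il18r1, Gimap7, Cxcr3, S1pr4, Tbc1d10c, Tcf7 and Gimap8. Their log2 fold changes ran from -3.58 ± 0.98 (SE) for Traf3ip3 to -2.13 ± 0.45 for Gimap8. Cxcr3, a chemokine receptor of activated T cells, was at -2.54 ± 0.57, and Tcf7, a transcription factor of T cells, at -2.26 ± 0.64 (adjusted p = 0.0124 and 0.0495). Over all 3391 genes, called or not, 57.2% had the same sign in both pairs of suspensions. With every library weighted to the same cell type composition, limma called 12 genes, 11 of them among the 135, while 131 of the 135 kept their sign. This fit changed the test as well as the composition, so the smaller number of calls cannot be credited to composition. With libraries thinned to the smallest total 55 of the 135 genes were still tested, all with the same sign, and 24 of them were called. With DESeq2's Wald test 60 genes were called, and with aliquots summed to 4 suspensions 89, 83 of them among the 135.

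Immediate-early genes, which cells transcribe within minutes of a stimulus, rose as a list. Of 29 measured members 6 were higher at 37C (15 adjusted over the list alone) and 0 lower, with a camera adjusted p of 2.4e-10 and 0.0153 with an estimated correlation. Jun was higher by 2.63 ± 0.40 on the log2 scale (adjusted p = 0.000373). Fosb, with 2 counts at 4C, was 20.6-fold higher (95% counting interval 6.92 to 211), and Atf3, with 3, 10.3-fold (2.86 to 42.5). Nr4a2 had 1 count at 4C and was 17.4-fold higher (2.96 to 685). Egr1 (1.93 ± 0.78, adjusted p = 0.198) and Ier3 (0.55 ± 0.38, adjusted p = 0.519) did not pass. With every library thinned to the smallest total, 3 members were still measured and the list did not pass (camera adjusted p = 0.188).

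Inflammatory NF-kB genes also rose, with 10 of 19 members higher (12 adjusted over the list alone) and 0 lower. The camera adjusted p was 1.3e-12, and 0.0153 with an estimated correlation. With every library thinned to the smallest total, 3 members were still measured and the list did not pass (camera adjusted p = 0.0976). The monocyte chemokine gene Ccl2 was higher by 4.08 ± 0.47 on the log2 scale (adjusted p = 1.8e-05), Il1b by 2.76 ± 0.63 (0.0126), Cd14 by 2.98 ± 0.50 (0.000927) and Nfkbia, an NF-kB inhibitor, by 1.39 ± 0.28 (0.00549). The share of macrophages differed in the same direction, as given above. Macrophage markers had 9 of 12 members higher (9 adjusted over the list alone, with 1 lower) and a camera adjusted p of 7.9e-17, but 0.129 with an estimated correlation. Examples are Apoe (2.84 ± 0.37, adjusted p = 4.6e-05) and Lyz2 (1.90 ± 0.40, adjusted p = 0.00847). T-cell markers had 3 of 11 members lower, Cd8b1, Trbc1 and Cd3g (8 adjusted over the list alone). Their camera adjusted p was 3.5e-09, and 0.129 with an estimated correlation. With every library weighted to the same cell type composition, 6 of the 11 T-cell markers had a positive log2 fold change, with a median of 0.03 and a camera p of 0.437 (unadjusted). In the same fit the camera p was 4.2e-08 for immediate-early, 1.7e-08 for inflammatory and 0.000139 for macrophage genes. At 4C the macrophage part of this fit rests on 8 and 3 cells without inhibitor and 1 and 5 with it (A and B). NK-cell markers had 2 of 5 lower, Gzmb (-1.92 ± 0.41) and Gzma (-1.55 ± 0.30), and 3 adjusted over the list alone. Their camera adjusted p was 4.2e-05, and 0.272 with an estimated correlation.

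Heat shock genes did not pass as a list (0 of 12 called, camera adjusted p = 0.111), with Hspa1b at 2.82-fold in mean CPM (adjusted p = 0.142) and Dnajb1 at 0.86 ± 0.63 (0.549). Hspa1b is nearly identical in sequence to Hspa1a, which had 10 counts in all and was not tested. Of the cold-inducible pair, Cirbp was at -1.01 ± 0.55 (adjusted p = 0.379) and Rbm3, with 38 counts, was not tested. No member was called among p53 targets (5 measured, camera adjusted p = 0.561), unfolded-protein genes (11, 0.265), cell cycle genes (14, 0.276), NRF2 targets (9, 0.0673) and mitochondrially encoded genes (4, 0.111). The same held for tumour epithelial (3, 0.276), fibroblast (3, 0.115), dendritic (2, 0.932) and mast-cell markers (5, 0.111). In these lists camera's p in the main fit did not pass either. Some alternative settings of the list test did call heat shock, cell cycle or mitochondrially encoded genes. Over all barcodes camera called heat shock (adjusted p = 0.000155), cell cycle (1.5e-06), NRF2 (0.000206) and tumour epithelial genes (0.00232) higher. Mitochondrially encoded genes were lower there (0.00202). In fry, which does not compare a list with other genes, heat shock, unfolded-protein and NRF2 genes were higher (adjusted p = 0.04905 each). With the replicate letter as a block, camera called NRF2 targets (adjusted p = 0.0350) and mast-cell markers (0.0114) higher. With an estimated correlation, and no block, the adjusted p was 0.294 for heat shock genes, 0.459 for unfolded-protein genes, 0.272 for NRF2 targets and 0.609 for mast-cell markers. At an unadjusted p under 0.05, 555 of all 3391 genes passed in edgeR. Of 18 hypoxia and glycolysis genes Tpi1 was higher (camera adjusted p = 0.757), and of 12 interferon genes Ifitm3 (0.470). Ribosomal protein genes, with 73 measured, did not pass as a list (camera adjusted p = 0.111), and 3 of them were higher. The 8 lists with fewer than 2 tested genes had no list test in the main fits, though some were tested in alternatives. Over all barcodes, 2 B-cell markers were measured and did not pass for temperature (camera adjusted p = 0.1996). They were lower with inhibitor at 37C (3.5e-05). Endothelial markers, 3 of them measured, did not pass for temperature (0.9811) and were higher with inhibitor at 37C (0.00396). Neutrophil markers had 1 tested gene, Mmp9, which was higher (2.96 ± 0.62, adjusted p = 0.00808). Endothelial markers had 147 UMIs in all annotated cells, B-cell markers 128, pericyte and smooth muscle markers 31, skeletal muscle markers 15, adipocyte markers 8 and erythroid markers 0.

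The temperature effect was then taken without and with the inhibitor, in separate suspensions. Without inhibitor, 33 genes were higher at 37C and 3 lower, Ccnd3, Irgm1 and Leprotl1, which lie outside the naming rule and were picked after their values were seen. Fos, with 169 counts at 37C and 0 at 4C, was at least 20.7-fold higher, Nr4a3 at least 10.0-fold and Nr4a2 at least 5.88-fold. Jun was higher by 3.06 ± 0.53 (adjusted p = 0.00428) and Nfkbia by 2.34 ± 0.37 (adjusted p = 0.00173). Of the 29 immediate-early genes 10 were higher (21 adjusted over the list alone), with a camera adjusted p of 3.7e-33 and 0.00273 with an estimated correlation. Of 19 inflammatory genes 5 were higher (13 adjusted over the list alone), with 7.4e-20 and 0.00464. Macrophage markers had 3 of 12 higher (4 adjusted over the list alone; camera adjusted p = 1.6e-06, and adjusted p = 0.297 with an estimated correlation). T-cell markers had 0 of 11 called (camera adjusted p = 0.530). NK-cell markers were lower and dendritic-cell markers higher in the camera test (adjusted p = 0.0428 each). With an estimated correlation these gave an adjusted p of 0.593 and 0.297, and of the dendritic pair Ccr7 was called. With libraries thinned to the smallest total 14 of the 36 genes were still tested and 0 called. The immediate-early and inflammatory lists, with only 3 members of each measured, were higher there (camera adjusted p = 0.00205 and 0.0101). DESeq2's Wald test called 20 of the 36, and without the 37C library without inhibitor B 18 of them were called.

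With inhibitor, 34 genes were higher at 37C and 27 lower. Of the 29 immediate-early genes 0 were called (1 adjusted over the list alone; camera adjusted p = 0.552), with Jun at 2.19 ± 0.61 (adjusted p = 0.0725) and Fos at 1.98 ± 0.62 (adjusted p = 0.134). At an unadjusted p under 0.05, 463 of the 3391 genes passed in edgeR. Inflammatory genes had 2 of 19 higher, Ccl2 and Ccl7 (3 adjusted over the list alone). Ccl2, with 1 count at 4C, was 39.5-fold higher (95% counting interval 9.94 to 2210). The list's camera adjusted p was 0.00164, and 0.139 with an estimated correlation. Macrophage markers had 9 of 12 higher (9 adjusted over the list alone, with 2 lower; camera adjusted p = 1.9e-16, and adjusted p = 0.139 with an estimated correlation). Arg1, with 0 counts at 4C, was at least 35.0-fold higher and C1qa at least 11.1-fold. T-cell markers had 3 of 11 lower, Cd8b1, Trbc1 and Trbc2 (11 adjusted over the list alone; camera adjusted p = 7.6e-15, and adjusted p = 0.139 with an estimated correlation). At the same cell type composition the camera p (unadjusted) was 0.207 for T-cell markers, 0.0654 for inflammatory genes and 0.000115 for macrophage markers, with 10 of 12 positive. The macrophage part of that fit rests on 1 and 5 cells (A and B) at 4C with inhibitor. NK-cell markers had 1 of 5 lower, Gzma (camera adjusted p = 0.000131, and adjusted p = 0.364 with an estimated correlation). Ribosomal protein genes had 1 of 73 higher, Rpl30 (camera adjusted p = 0.00164), and mast-cell markers 0 of 5 (0.0473). Each had an adjusted p of 0.602 with an estimated correlation. Genes called in both pairs of suspensions numbered 10, all higher at 37C, where independent lists would share 0.331. That value takes every gene as equally likely to be called. It is not matched for abundance, so the excess over it cannot be read as replication alone. Without the 4C library with inhibitor B, 10 genes were called in place of 61.

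At 37C, the inhibitor comparison asks which transcripts differ when the inhibitor is present during warm dissociation. How far it blocked transcription was not measured. Immediate-early genes were lower with inhibitor. They took 0.893% ± 0.0732 of annotated UMIs without and 0.344% ± 0.0424 with it, against 0.281% ± 0.0169 and 0.332% ± 0.0235 at 4C (SD, n = 2 libraries each). Of 29 members 12 were lower (25 adjusted over the list alone) and 0 higher, with a camera adjusted p of 1.3e-41 and 0.00171 with an estimated correlation. Nr4a3 (ENSMUSG00000028341.9, chromosome 4, 48045153 to 48086447) fell by 3.56 ± 0.63 on the log2 scale (adjusted p = 0.00427), Ier5 by 2.27 ± 0.35 (0.00139), Fosb by 2.08 ± 0.35 (0.00278) and Klf2 by 1.65 ± 0.31 (0.00502). Fos (-0.90 ± 0.33, adjusted p = 0.303) and Jun (-0.48 ± 0.31, adjusted p = 0.798) did not pass.

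**Figure D2:**
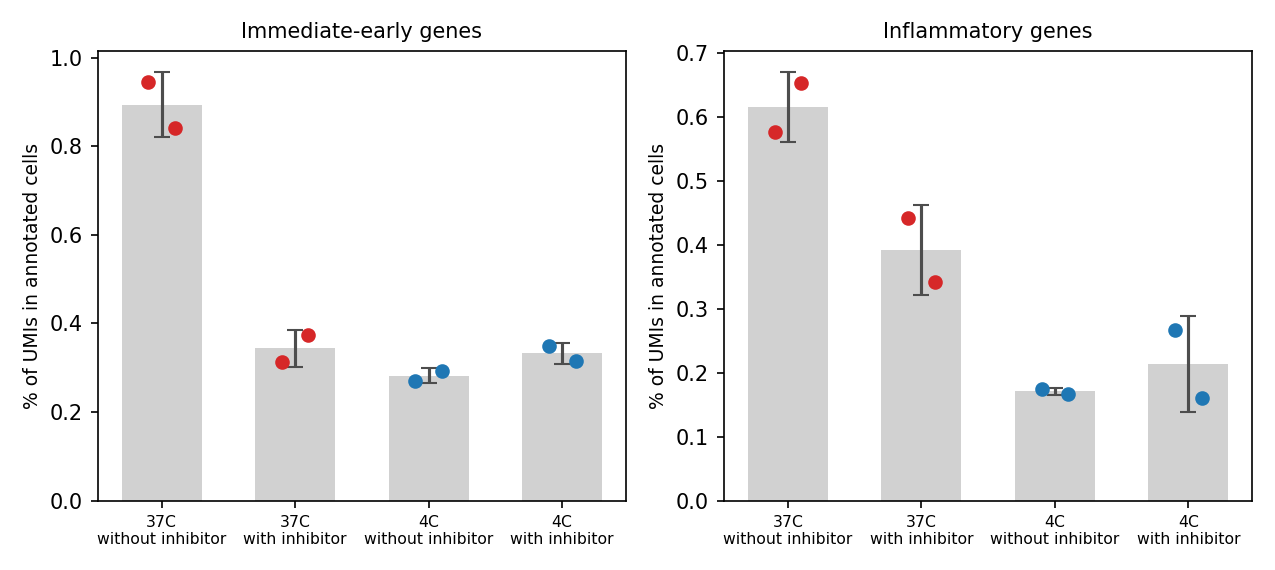
Share of annotated UMIs (percent, vertical axis) from the members of gene lists in the 4 groups; points are libraries, bars the mean of 2 libraries and error bars the SD. Immediate-early genes lie at 0.893% at 37C without inhibitor and at 0.281% to 0.344% in the other 3 groups.

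In all, 5 genes were higher with inhibitor at 37C and 36 lower. Csf2 (ENSMUSG00000018916.5, chromosome 11, 54247271 to 54249667), a growth factor of granulocytes and macrophages, had 57 counts without and 0 with inhibitor and was at least 22.9-fold lower. Ccr7, a chemokine receptor of naive T cells and dendritic cells, went from 282 ± 18.7 to 3.26 ± 4.61 CPM, a ratio of 0.0116 (95% counting interval 0.000288 to 0.0663). Nfkbid and Cd8b1 were the other decreases named by the rule, at ratios of 0.0212 (0.000526 to 0.126) and 0.0534 (0.00621 to 0.211). The 5 increases were C1qc (2.41 ± 0.42, adjusted p = 0.0037), C1qb, C1qa, Ccl6 and Lgmn, of which the first 3 encode the chains of complement C1q. Inflammatory genes had 3 of 19 lower, Tnfaip3, Cxcl3 and Nfkbia (5 lower and 1 higher adjusted over the list alone; camera adjusted p = 1.8e-06, and adjusted p = 0.0474 with an estimated correlation). In the thinned libraries, with 3 members measured, the inflammatory list did not pass (camera adjusted p = 0.0534). Macrophage markers had 3 of 12 higher (7 adjusted over the list alone; camera adjusted p = 3.2e-13, and adjusted p = 0.125 with an estimated correlation). T-cell markers had 2 of 11 lower, Cd8b1 and Cd8a (8 adjusted over the list alone; camera adjusted p = 5.4e-12, and adjusted p = 0.0817 with an estimated correlation). At the same cell type composition the camera p (unadjusted) was 0.789 for T-cell markers, 2.1e-08 for inflammatory genes, with 2 of 19 positive, and 0.000481 for macrophage markers, with 11 of 12 positive. NK-cell markers (0 of 5 called, camera adjusted p = 0.0140) and dendritic-cell markers (Ccr7 lower, 5.7e-06) were also lower, with an adjusted p of 0.498 and 0.0586 with an estimated correlation. T cells were 24.1% ± 5.86 of cells without and 9.60% ± 0.956 with inhibitor at 37C (SD, n = 2), and macrophages 16.5% ± 2.40 and 26.1% ± 6.66. With DESeq2's Wald test 8 of the 41 genes were called. With libraries thinned to the smallest total 4 of the 41 were still tested, all with the same sign, and 0 were called. The comparison shares the uninhibited 37C libraries with the temperature effect without inhibitor, so the 2 are not independent.

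At 4C, no gene was called for the inhibitor by edgeR (172 of 3391 at an unadjusted p under 0.05) or by DESeq2's Wald test (0 genes). Immediate-early genes had 0 of 29 called (camera adjusted p = 0.435), and Jun was at 0.39 ± 0.93 (adjusted p = 0.994). Mast-cell markers were lower in the camera test (adjusted p = 0.000181, and adjusted p = 0.776 with an estimated correlation), with 427 UMIs without and 4 with inhibitor, of which 417 came from library A. Ribosomal protein genes were lower (camera adjusted p = 0.00545) and T-cell markers higher (0.0429), each with an adjusted p of 0.776 with an estimated correlation and 0 members called. With every gene tested and no filter, 11 genes were called, and without the 4C library without inhibitor B, 12.

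The interaction tests whether the inhibitor's effect differed between temperatures. No single gene was called by edgeR (250 at an unadjusted p under 0.05, smallest adjusted p 0.0663) or by DESeq2's Wald test (0 genes). As a list, immediate-early genes had a lower log2 change with inhibitor at 37C than at 4C, where the list did not pass (0 of 29 called for the interaction, 2 lower adjusted over the list alone). The camera adjusted p was 3.4e-10, and 0.0305 with an estimated correlation. Median log2 interaction was -1.64, with Fos at 5 counts or fewer in both 4C groups. Without a filter on low counts 14 genes were called, and without the 4C library without inhibitor B, 17.

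In tumour cells alone, Fos and Fosb were higher at 37C. Fos had 1130 ± 445 and 511 ± 177 CPM at 37C without and with inhibitor, against 0 counts and 105 ± 20.3 CPM at 4C (SD, n = 2 libraries each). Fosb had 829 ± 259 and 176 ± 6.87 CPM against 0 counts and 45.3 ± 64.0. The chemokine gene Cxcl1, with 3 counts at 4C, had 341 ± 83.7 and 255 ± 190 CPM at 37C against 32.8 ± 46.4 and 45.3 ± 64.0 at 4C (adjusted p = 0.0176). The decreases named were Neat1 (-1.27 ± 0.33), Abhd2 (-1.15 ± 0.27) and Cd74 (-1.10 ± 0.30). Of 1756 genes, 16 were higher and 9 lower. Of 18 immediate-early genes 4 were higher (10 adjusted over the list alone; camera adjusted p = 2.4e-12, and adjusted p = 0.0811 with an estimated correlation).

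Without inhibitor, 24 genes were higher in tumour cells at 37C and 13 lower, and 9 of the 18 immediate-early genes were higher (camera adjusted p = 1.2e-24, and adjusted p = 0.0281 with an estimated correlation). With inhibitor 0 were higher and 1 lower, Slpi, a protease inhibitor (-1.08 ± 0.21, adjusted p = 0.00654), which was named after its value was seen. With inhibitor at 37C, 15 genes were lower and 1 higher, H2-Aa (2.30 ± 0.59, adjusted p = 0.0307), likewise named afterwards. Immediate-early genes then had 8 of 18 lower (16 adjusted over the list alone), with a camera adjusted p of 2.8e-38 and 0.00341 with an estimated correlation. Examples were Fosb (-2.21 ± 0.36), Atf3 (-2.03 ± 0.45) and Junb (-1.36 ± 0.30). At 4C the inhibitor gave 0 calls in edgeR (90 at an unadjusted p under 0.05) and 0 in DESeq2, and so did the interaction in edgeR (121). DESeq2's Wald test called 7 genes for temperature, 2 without inhibitor and 1 for the inhibitor at 37C. No filter gave 120 genes for temperature.

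In T cells, with 230 genes tested, 16 were higher at 37C and 6 lower. Ctla4, an inhibitory receptor of activated T cells (ENSMUSG00000026011.13, chromosome 1, 60887000 to 60915832), had 2580 ± 540 and 2430 ± 1820 CPM at 37C without and with inhibitor, against 743 ± 695 CPM and 0 counts at 4C (SD, n = 2 libraries each). The interleukin-2 receptor gene Il2ra was at 2.47 ± 0.59 on the log2 scale and Ly6a at 2.20 ± 0.51 (adjusted p = 0.0169 each). The decreases named were Ly6c2 (-2.73 ± 0.78), Mcl1 (-2.48 ± 0.57) and Selplg (-1.26 ± 0.38). Without inhibitor 1 gene, Nfkbia, was higher at 37C (3.78 ± 0.58, adjusted p = 0.00155), and with inhibitor 1, Cd2 (2.73 ± 0.53, adjusted p = 0.0218). Nfkbia (-3.11 ± 0.52, adjusted p = 0.00454) and Ccr7 (68 counts without and 0 with inhibitor, adjusted p = 0.0359) were lower with inhibitor at 37C. Nfkbia, Cd2 and Ccr7 were named in these 3 comparisons after their values were seen. The inhibitor at 4C gave 0 calls in edgeR (14 at an unadjusted p under 0.05) and 0 in DESeq2, and the interaction 0 in edgeR (12). DESeq2's Wald test called 5 genes for temperature. Without the 37C library with inhibitor A, 2 genes were called for temperature in place of 22.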

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

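Chosen only after the result was seen were the tests of the immediate-early genes against composition and suspension, the set of their share against library totals, the tests of large barcodes against depth and against cell types, and the counts of other splits. The test of these genes in thinned libraries, the 2 tests of the macrophage share, and that of large barcodes against random pairs of cells were written before their results.

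Immediate-early genes were lower with inhibitor at 37C, and the effect of temperature on this list differed with against without inhibitor (camera adjusted p of the interaction 3.43e-10). A change in cell type composition alone is argued against by tumour cells, in which the list was lower (camera adjusted p = 2.80e-38). Library depth is argued against by the share of UMIs, which was at least 0.842% without and at most 0.373% with inhibitor, a ratio of 2.25, while the totals of the 37C libraries differed by at most 1.26-fold. With every library thinned to the smallest total the list was lower too (camera adjusted p = 0.000102), with only 3 of its 29 members still measured; a further test with the 37C libraries alone thinned, made after that was seen, changed their depth little and was dropped. With 1 suspension per condition, an effect of the inhibitor and another difference between the suspensions cannot be told apart.

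Macrophages held a larger share of annotated cells at 37C in all 4 libraries, and were not past 0.05 after adjustment over the 4 types. That macrophages at 4C were left out of the annotation stays open. Their markers over all barcodes took 0.569% ± 0.192 of UMIs at 37C and 0.245% ± 0.0274 at 4C (SD, n = 4). The exact permutation p was 0.0286. This share follows the number of macrophages only if each holds equal shares of these markers at both temperatures. At the same cell type composition 8 of 12 markers had a positive log2 fold change, with a median of 2.23. That fit rests on few macrophages at 4C, and the marker share cannot decide. A minimum number of UMIs per cell stays open: with 37C cells thinned to the depth at 4C, the share was 18.8% ± 6.59 against 7.45% ± 4.92 (exact permutation p = 0.0571). Temperature, suspension and instrument changed together, so the biological explanation was not tested apart from them.

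Outside the annotated cells, 104 barcodes at 37C and 1 at 4C held over 5000 UMIs. In the 37C libraries these barcodes held 30.0% to 43.1% of all UMIs, and the annotated cells 24.9% to 36.5%. Library depth stays open as an explanation. A limit scaled to the 4C depth, 2391 UMIs, was set at 4C, with annotated barcodes counted too. All 4 libraries at 4C had 0 to 8.47 barcodes over it per 100 annotated cells. The lowest library at 37C had 16.16 over 5000. The scale, 0.478, was the ratio of median UMIs of annotated cells, 4C to 37C. Annotated cells held at most 4963 UMIs, so the scale leaves out the large barcodes themselves, and this limit cannot decide. An earlier form of this test, which left annotated barcodes out, was void and was replaced. Random pairs of annotated cells are argued against by T-cell markers, whose share lay below the range of such pairs in 4 of 4 libraries at 37C; pairs of tumour cells would lack these markers too and stay open. The barcodes may be tumour cells above an upper UMI limit of the annotation, single or paired, since in 4 of 4 libraries their summed profile correlated best with annotated tumour cells (r across genes 0.805 to 0.840, against at most 0.341 for the other types; genes are not independent replicates).

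Other lists also had a temperature effect that differed with against without inhibitor in the camera test of the interaction. Over all cells the adjusted p was 0.00733 for inflammatory NF-kB genes, 1.27e-11 for T-cell markers, 0.00101 for ribosomal protein genes, 0.000514 for macrophage markers and 0.0243 for mast-cell markers. With an estimated correlation these gave an adjusted p of 0.171, 0.171, 0.683, 0.622 and 0.662. At the same cell type composition the interaction had a camera p, unadjusted, of 0.158 for T-cell markers, 3.3e-05 for inflammatory genes and 0.0157 for macrophage markers. That fit rests on 1 to 8 macrophages per library at 4C. In tumour cells the camera adjusted p of the interaction was 6.59e-06 for immediate-early, 0.00031 for interferon and 2.80e-05 for ribosomal protein genes. With an estimated correlation it was 0.193, 0.193 and 0.692. The reporter sequences luc2 and HygroR had 4 and 9 UMIs over all barcodes.

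For temperature, the 8 libraries can be split into 4 and 4 in 35 ways, and a fit with 2 groups was made for each. Over all cells the real split called 99 genes and the highest other 5, in tumour cells 20 and 8, and in T cells 8 and 1. In each case 1 split, the real one, called as many. Aliquots of a suspension are not independent, and only 3 splits keep them together, which are too few for a share under 0.05. In tumour cells another of these 3 splits called 7 genes.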

How the results depend on the processing

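Thinning every library to the smallest total and adding the barcodes over 5000 UMIs were chosen after the results were seen. Of the alternatives for 42 named-gene results, 451 kept their call, 148 lost it and 0 changed direction. Alternatives in which a gene was no longer tested are in neither count, so genes with low counts have fewer. Fos for temperature over all cells had 17 kept and 0 lost, and Nfkbid for the inhibitor at 37C 8 and 1. Some named genes lost their call for temperature more often than they kept it. In tumour cells Neat1 had 4 kept and 9 lost, and in T cells Selplg had 4 and 9. Over all cells Tcf7 had 4 and 8, and Rhof 7 and 9. On simulated data the test of the inhibitor at 4C called 46 genes and recovered 4% of 2-fold and 37% of 4-fold changes, and whether depth or small effects gave its 0 calls was not tested. After thinning 55 of the 135, 14 of the 36 and 4 of the 41 genes called for temperature, for temperature without inhibitor and for the inhibitor at 37C were still tested. For the other changes below the cause was not tested. A library left alone in its group is assumed to vary like the other groups.

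For the temperature effect, all cells, 135 genes were called. The alternatives gave 60 with DESeq2's Wald test, 89 with 4 suspensions, 1290 with all barcodes, 286 with barcodes over 5000 UMIs added, 25 with thinned libraries, 293 with no filter and 12 at the same composition. Leaving out each library gave 80 to 198, with 80 without 37C no inhibitor B and 85 without 4C with inhibitor B. For the temperature effect without inhibitor, all cells (36 genes), they gave 22 with DESeq2's Wald test, 349 with all barcodes, 0 thinned, 85 with no filter and 56 with the replicate block, and 23 to 58 with a library left out. Counts were 58 and 57 without 37C with inhibitor A and B, 23 without 37C no inhibitor B, and 56 without 4C no inhibitor A. For the temperature effect with inhibitor, all cells (61), they gave 33, 795 and 147 with DESeq2's Wald test, all barcodes and added barcodes, 9 thinned and 135 with no filter. Leaving out a library gave 10 to 165, with 10 without 4C with inhibitor B, and 165 and 159 without 4C no inhibitor A and B.

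For the inhibitor effect at 37C, all cells (41), DESeq2's Wald test gave 8, all barcodes 256, thinning 0 and no filter 75. Leaving out a library gave 15 to 116, with 27 without 37C with inhibitor B, 15 and 21 without 37C no inhibitor A and B, and 114 and 116 without 4C no inhibitor A and B. For the inhibitor effect at 4C, all cells (0), all barcodes gave 2, no filter 11 and the replicate block 5. Leaving out a library gave 0 to 12, with 6 each without 37C with inhibitor A and B, and 3 and 12 without 4C no inhibitor A and B. For the temperature by inhibitor interaction, all cells (0), all barcodes gave 87, no filter 14 and the block 2. Leaving out a library gave 0 to 17, with 4 and 3 without 37C with inhibitor A and B, 2 without 37C no inhibitor A, and 1 and 17 without 4C no inhibitor A and B.

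In T cells, the temperature effect, T cells (22) gave 14 with 4 suspensions, 5 with DESeq2's Wald test and 14 with no filter. Leaving out a library gave 2 to 24, with 2 and 11 without 37C with inhibitor A and B, and 5 each without 4C with inhibitor A and B. The temperature effect without inhibitor, T cells (1) gave 15 with no filter, 9 with the replicate block and 1 to 12 with a library left out (4 and 6 without 37C no inhibitor A and B, 7 without 4C with inhibitor B, 9 and 12 without 4C no inhibitor A and B). The temperature effect with inhibitor, T cells (1) gave 0 with DESeq2's Wald test, 2 with no filter, 11 with the block and 0 to 18 with a library left out. It gave 0 without either 37C or 4C library with inhibitor, 6 and 5 without 37C no inhibitor A and B, and 11 and 18 without 4C no inhibitor A and B. The inhibitor effect at 37C, T cells (2) gave 1 with DESeq2's Wald test, 10 with no filter, 4 with the block and 0 to 13 with a library left out. It gave 0 without either 37C library with inhibitor, 7 without 37C no inhibitor A, 5 and 6 without 4C with inhibitor A and B, and 9 and 13 without 4C no inhibitor A and B. The inhibitor effect at 4C, T cells gave 0 to 1 (1 without 4C no inhibitor B).

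In tumour cells, the temperature effect, tumour cells (25) gave 7 with DESeq2's Wald test, 120 with no filter and 12 to 63 with a library left out (12 without 37C with inhibitor B, 63 without 4C with inhibitor B, 62 and 55 without 4C no inhibitor A and B). The temperature effect without inhibitor, tumour cells (37) gave 2 with DESeq2's Wald test and 11 to 46 with a library left out (16 without 37C no inhibitor B, 17 and 11 without 4C no inhibitor A and B). The temperature effect with inhibitor, tumour cells (1) gave 0 with DESeq2's Wald test, 23 with no filter and 0 to 19 with a library left out. It gave 0 and 3 without 37C with inhibitor A and B, 2 and 7 without 37C no inhibitor A and B, 0 and 11 without 4C with inhibitor A and B, and 19 and 15 without 4C no inhibitor A and B. The inhibitor effect at 37C, tumour cells (16) gave 1 with DESeq2's Wald test and 4 to 20 with a library left out (4 and 7 without 37C with inhibitor A and B, 6 and 8 without 37C no inhibitor A and B). The inhibitor effect at 4C, tumour cells (0) gave 0 to 1, with 1 without each 37C library. Requiring at least 10 cells per library gave 2 types for the temperature effect within each cell type and 2 for the inhibitor effect within each cell type, against 0 at 20.

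Of the lists, the temperature effect called 5, 2 with an estimated correlation, 7 with fry, 3 in tumour cells alone and 5 to 10 with a library left out (10 and 8 without 4C no inhibitor A and B, 8 without 4C with inhibitor A). Without inhibitor 5 were called, 2 with an estimated correlation, 2 with fry, 3 in tumour cells and 4 to 10 with a library left out (10 and 9 without 4C no inhibitor A and B, 8 without 4C with inhibitor A or B). With inhibitor 6 were called, 0 with an estimated correlation or fry, 1 in tumour cells and 3 to 9 with a library left out (3 without 4C with inhibitor B). For the inhibitor at 37C 6 were called, 2 with an estimated correlation, 3 with fry, 2 in tumour cells and 6 to 10 with a library left out (10 without 37C with inhibitor A or either 4C no inhibitor library). At 4C 3 were called, 0 with an estimated correlation or fry, and 1 to 5 with a library left out (1 without 4C with inhibitor A, 5 without 4C no inhibitor B). For the interaction 6 were called, 1 with an estimated correlation or fry, 3 in tumour cells and 5 to 10 with a library left out (10 without 4C with inhibitor A).

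The share difference between temperatures, in percentage points, was 13.86 for macrophages, 37.15 among cells other than tumour cells (then past 0.05) and 10.68 to 16.03 with a library left out. For T cells it was -21.24, -26.47 among those cells (then past 0.05) and -25.04 to -18.25, for NK cells -11.15 to -5.445 and for tumour cells 11.8 to 20.62. Without 37C no inhibitor A, macrophages (14.9), T cells (-25.04) and tumour cells (20.62) passed 0.05. For the inhibitor, differences changed sign. Macrophages ran from -1.435 (without 37C with inhibitor A) to 7.865, NK cells from -5.933 to 2.114 (0.217 and 2.114 without 37C with inhibitor A and B, 0.1392 without 4C no inhibitor A). T cells ran from -10.41 to 2.301 (1.851 and 2.301 without 37C with inhibitor A and B). Tumour cells ran from -6.118 to 7.242 (-0.7912 without 37C no inhibitor A, -0.6331 and -6.118 without 37C with inhibitor A and B, -1.037 without 4C no inhibitor A).

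Per cell, the temperature difference in the number of cells (53) was 4.5 over all barcodes and 45.92 to 59.25 with a library left out. That in median UMIs (706.6) ran from 600.3 to 801.6, and that in median genes (374.6) was -1.375 with cells thinned to 200 UMIs and 321.1 to 413.8 with a library left out. With the replicate block 53, 706.6 and 374.6 were no longer past 0.05, since the smallest permutation p within the letters is 0.0556. Percent mitochondrial (0.03302) was -0.1221 over all barcodes and 0.01657 to 0.05695 with a library left out. For the inhibitor, cells ran from -21.75 to 4.25 (without 4C with inhibitor A). Median UMIs were -0.25 over all barcodes and -77.83 (without 37C with inhibitor A) to 275.5, and median genes -0.875 thinned, -1.5 over all barcodes and -50.17 (without 37C with inhibitor A) to 135.5. Percent mitochondrial ran from -0.05052 to -0.01224. The letters A and B name aliquots, and differences between the letters correlated across genes between groups at -0.0278 to 0.239.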

Other observations

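The threshold for mast-cell markers was chosen only after the result was seen, and the rest are values with no test of an explanation. Of 1587 UMIs of mast-cell markers, 1552 lay in 7 cells with at least 10 such UMIs, all annotated as macrophages. By library they numbered 2 and 1 at 37C without inhibitor (A and B), 2 and 0 at 37C with inhibitor, 2 and 0 at 4C without inhibitor, and 0 and 0 at 4C with inhibitor. Without these cells macrophages took 20.1% ± 6.69 of annotated cells at 37C and 6.61% ± 3.64 at 4C (SD, n = 4, two-sided exact permutation p = 0.0286, unadjusted).

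Interferon genes in tumour cells took 0.294% ± 0.0506 and 0.358% ± 0.00357 of UMIs at 37C without and with inhibitor, and 0.435% ± 0.0292 and 0.265% ± 0.0505 at 4C (SD, n = 2 libraries each). Of 7 measured members 0 were called for temperature without inhibitor, and 4 were lower adjusted over the list alone (camera adjusted p = 0.000593, and adjusted p = 0.0937 with an estimated correlation). For the inhibitor at 4C 0 were called, and 2 were lower adjusted over the list alone (camera adjusted p = 0.00312, and adjusted p = 0.594 with an estimated correlation).

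In NK cells, immediate-early genes took 0.956% ± 0.218 and 0.717% ± 0.0939 of UMIs at 37C without and with inhibitor, and 0.325% ± 0.0257 and 0.351% ± 0.0703 at 4C (SD, n = 2 libraries each, not tested). The 37C value with inhibitor rests on 10 NK cells, 8 in A and 2 in B. In T cells they took 1.01% ± 0.0254 and 0.272% ± 0.00276 at 37C. The first principal component held 32.7% of the variance, and on it 4C with inhibitor A, the smallest library, lay at 51.2 and the other 7 libraries between -15.1 and 8.45. In the unannotated barcodes over 5000 UMIs at 37C, immediate-early genes took 0.873% ± 0.00765 of UMIs without and 0.344% ± 0.0224 with inhibitor (SD, n = 2 libraries each).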
